A study of Homo sapiens with 6 samples.

How the data were processed

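The libraries hold RNA from the chromatin fraction of H9 human embryonic stem cells. Per the labels' protocols, cells were fractionated, RNA was extracted on columns, and libraries were made with a directional kit that keeps strand. Per the submitters' processing notes, the tools named are Trimmomatic 0.39 (read trimming), STAR 2.7.8a (alignment), featureCounts and Subread 2.14.2 (counting). The genome build, the repeat annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Shared reads can therefore move between near-identical families, and a directional count cannot be told from a count of both strands.

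The deposited values are raw counts, whole numbers per repeat name and library, which the authors did not normalise as far as the values show. Each entry adds up all copies of a repeat, so genomic positions were not analysed here. Because the entries are repeats and not genes, the gene lists, long non-coding genes and always-named genes fixed before the data were examined matched 0 entries. In their place, 31 lists of repeat families were written after the entry names, the library totals and the counts of the 40 most abundant entries had been seen, and before any test was run. The composition result likewise used alpha satellite, ribosomal RNA, small nuclear and nucleolar RNA and the 10 most abundant entries. Groups come from the treatment label and columns were matched to samples by title.

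Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with the group, and the quasi-likelihood F-test of naive minus primed with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 change is its size divided by the square root of F. The CPM values given are TMM-normalised. Of 15641 entries, 3219 were tested, and these held between 99.7% and 99.9% of each library's counts. TMM factors were 0.903, 0.628 and 0.855 in naive libraries 1 to 3 and 1.10, 1.51 and 1.24 in primed libraries 1 to 3. Lists with at least 3 tested members, 28 in all, were tested with limma 3.58.1 camera (preset correlation 0.01, two-sided, log2 CPM with a prior count of 2), with an estimated correlation and fry as alternatives. The sizes given for lists are medians of edgeR log2 changes, because log2 CPM with a prior count shrinks values in the shallow primed library 2. The camera test calls 8 lists, and 0 with an estimated correlation. Mean and median differ in sign from the camera direction for the list of HERVFH, LTR6 and HERVH48 (mean 0.01, median 0.09, camera negative with adjusted p = 0.712). For AluJ the mean and median are below 0 (-0.02 and -0.01) and the camera direction is negative. Its mean minus that of other repeats is 0.12, however, and the direction is positive when camera is run on counts.

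Shares of counts were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Single shares carry 95% Wilson intervals. Intervals and count limits cover counting error only, since reads without molecular identifiers are not independent molecules. Named repeats follow a rule fixed before the data were examined, applied to repeats in place of genes: the 10 with the largest change in each direction (adjusted p under 0.05, mean CPM of at least 5, groups not overlapping), and up to 3 per list and direction. Of 123 higher and 7 lower repeats that met the first part, the text names some. Repeats named without a call (BSR, HSATII, LTR5A, LTR5B, LTR5, LTR7Y, LTR7B, LTR7C, L1HS, L1PA2, AluSx, AluYa5, AluYb8, SVA_E, SVA_F, 7SK) and the called Zaphod4a, tRNA-Arg-AGG and HERVIP10FH-int were chosen after the values were seen.

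The procedure was tested on simulated counts drawn from the means and library sizes of these 6 libraries, with 200 repeats changed. Among 3136 simulated repeats tested, 60.8% of 2-fold and 97.9% of 4-fold changes were called, and 2.58% of 155 calls were unchanged repeats. With 1 list doubled, 1 list was called and 0 wrongly. Each repeat was drawn independently of the others, with the spread that edgeR's trend gives to repeats of its abundance. The simulation therefore could not show how correlated repeats, repeats more variable than the trend or the shift of a single library affect the calls.

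Alternatives fixed before the data were examined were RLE, upper-quartile and no scaling factors, DESeq2 1.42.0, no filter or a CPM of at least 1 in 3 libraries, removal of ribosomal and small nuclear or nucleolar RNA, the replicate number as a block, glmTreat against a log2 of 1, and each library left out in turn. Chosen after seeing the data were leaving out simple repeats, leaving out alpha satellite and ribosomal RNA (from the library or from the total of a share), thinning all libraries to the total of primed library 2, DESeq2 on the main filter, and camera on counts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.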

Results

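Chromatin-bound RNA was sequenced from H9, an established human embryonic stem cell line, in a state labelled naive (RSeT medium) and in the primed state, with 3 libraries each. The labels give all 6 libraries the same RSeT growth protocol, so the primed state is taken from the treatment label. The table analysed here counts reads over repeat names, each summed over its genomic copies, so a value belongs to a repeat family and has no single coordinate. It has 15641 entries, of which 1343 are named repeats (transposable elements, satellites, structural RNAs) and 14298 are simple repeats named by their unit. Total counts were 9748202, 17791046 and 16700953 in naive libraries 1 to 3 and 7192242, 118793 and 8106871 in primed libraries 1 to 3. Primed library 2 was thus far shallower than the others, and 3 counts in it correspond to 25.3 CPM (counts scaled by the library total). Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

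The comparison asks how repeat RNA on chromatin differs between naive and primed cells. Alpha satellite (ALR/Alpha), the tandem repeat of human centromeres, took 34.2% ± 8.81 (SD, n = 3) of all counts in naive libraries and 0.384% ± 0.213 (SD, n = 3) in primed libraries. HERVK-int, the internal part of the youngest human endogenous retrovirus group (HML-2), was 12.3-fold higher in naive cells, and its long terminal repeat LTR5_Hs was 3.01-fold higher. HERVH-int, the internal part of a retrovirus group known for its transcription in human pluripotent cells, was 2.20-fold higher. With library size as the only scaling it did not pass (log2 0.42, edgeR adjusted p = 0.225). Of 263 simple repeats called, 235 were lower in naive cells, and so were 4 of 30 tRNA entries. Both counts rested on primed library 1, without which 6 simple repeats and 1 tRNA entry, tRNA-Gly-GGY, were called lower.

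Alpha satellite held 25.3%, 42.9% and 34.5% of counts in naive libraries 1 to 3, and 0.221%, 0.625% and 0.305% in primed libraries 1 to 3. The 95% Wilson interval for the shallow primed library 2 was 0.581% to 0.671%, which rests on 742 counts. The smallest p an exact two-sided permutation test of 3 against 3 can give is 0.1, and the alpha satellite shares gave that value. In the count model ALR/Alpha rose by 7.32 ± 0.40 (log2, SE), from 2875 ± 1128 CPM to 455900 ± 206660 CPM (SD, n = 3; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.34e-06). Its log2 change stayed between 6.94 and 7.68 when any 1 library was left out.

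**Figure D1:**
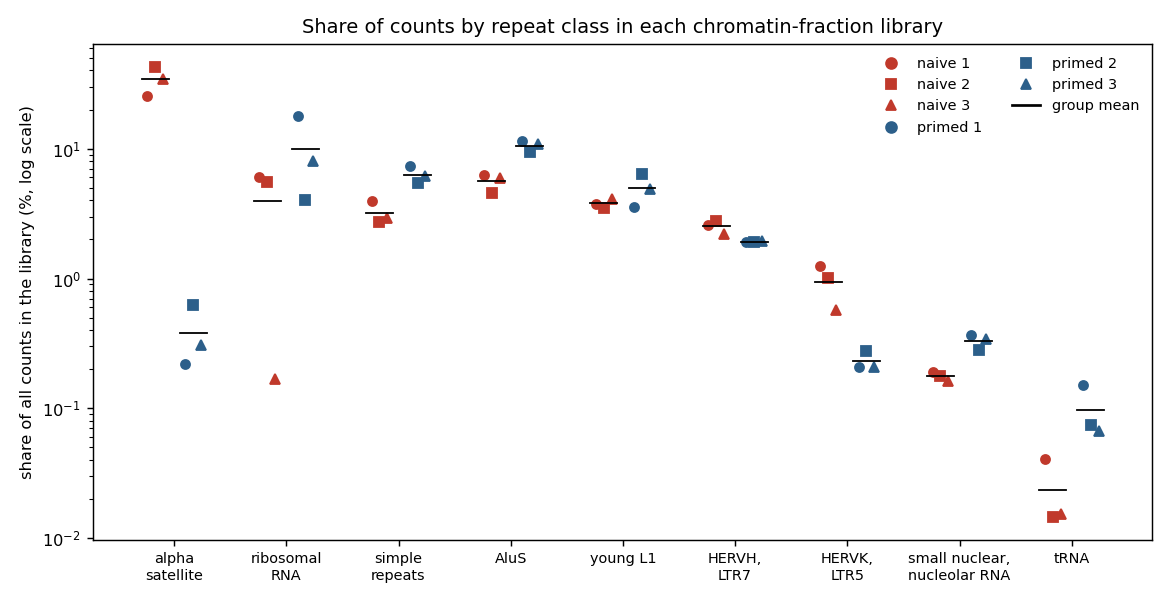
Share of all counts (percent, log axis) taken by 9 repeat classes in each library; red symbols are naive, blue symbols primed, symbol shape gives the library number and black lines the group means. Alpha satellite lies at 25.3% to 42.9% in the naive libraries and at 0.221% to 0.625% in the primed ones, while ribosomal RNA spans 0.169% to 6.08% within the naive libraries alone.

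The list of other satellites did not follow alpha satellite as a group. Of 30 tested satellite and centromere- or subtelomere-linked repeats outside alpha satellite, 3 rose, 0 fell and 27 did not pass the test. The 3 were ACRO1, a repeat of acrocentric chromosomes, with 3.71 ± 0.42 (log2, SE; edgeR adjusted p = 0.00136), HSATI with 1.22 ± 0.33 (edgeR adjusted p = 0.0353) and CER with 0.86 ± 0.19 (edgeR adjusted p = 0.0229). ACRO1 was rare, with 272 counts over the naive libraries and 11 over the primed ones, 0 of them in primed library 2. The beta satellite BSR stood at 715 ± 54.3 CPM in naive and 707 ± 183 CPM in primed libraries (log2 -0.01, edgeR adjusted p = 0.982), and HSATII at 9.14 ± 2.704 and 4.65 ± 1.62 CPM (log2 1.09, edgeR adjusted p = 0.0845). The list of these 30 did not pass as a whole (camera adjusted p = 0.203). The 10 simple repeats with GGAAT-type satellite units form a separate list, with a median of 0.82 (camera adjusted p = 0.106). That list passed as higher with library size alone (median 0.22, camera adjusted p = 0.0161) and by camera on counts (adjusted p = 0.0130). The HSATI and CER calls were lost without primed library 1. HSATI then gave a larger log2 change of 1.61 (edgeR adjusted p = 0.0969), and CER gave 0.69 (0.194). HSATI also missed the threshold without naive library 2 (0.94, 0.0794) or primed library 3 (0.89, 0.134), and CER without primed library 3 (0.84, 0.0618). With library size alone HSATI (0.58, edgeR adjusted p = 0.160) and CER (0.18, 0.634) did not pass, while ACRO1 did (3.17, 3.49e-06).

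Among the 5 HERVK (HML-2) and LTR5 entries, 2 rose, 0 fell and the other 3 did not pass. HERVK-int was at 10797 ± 4606 CPM in naive and 877 ± 97.4 CPM in primed libraries (log2 3.62 ± 0.30, SE; edgeR adjusted p = 7.88e-05). LTR5_Hs, the youngest terminal repeat of this group, was at 816 ± 269 and 272 ± 6.82 CPM (log2 1.59 ± 0.21; edgeR adjusted p = 0.00443). The related LTR5A (log2 -0.48, edgeR adjusted p = 0.123), LTR5B (0.11, 0.631) and LTR5 (-0.08, 0.792) did not pass, and whether LTR5_Hs differs from them was not tested. The list test gave a camera adjusted p of 0.177. Reads from near-identical copies can be shared among these entries, and how such reads were counted is not given in the sources used here. Both calls were kept in each of the 6 fits without 1 library, between 3.40 and 3.96 for HERVK-int and between 1.34 and 1.83 for LTR5_Hs. With library size alone HERVK-int stood at 2.91 (edgeR adjusted p = 1.57e-20) and LTR5_Hs at 0.87 (0.00697), and LTR5_Hs lost its call when all libraries were thinned to the total of primed library 2 (0.168).

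Among the 5 HERVH and LTR7 entries, 2 rose, 0 fell and 3 did not pass. HERVH-int was at 31271 ± 9805 CPM in naive and 14217 ± 2159 CPM in primed libraries (log2 1.14 ± 0.20, SE; edgeR adjusted p = 0.0106). LTR7, its terminal repeat, gave 0.87 ± 0.18 (edgeR adjusted p = 0.0156), while LTR7Y gave 0.56 (0.0686), LTR7B 0.01 (0.990) and LTR7C -0.31 (0.396). The list gave a camera adjusted p of 0.175. Without primed library 1 HERVH-int stayed past the threshold (1.22, edgeR adjusted p = 0.0320) and LTR7 did not (0.95, 0.0649). With library size as the only scaling, under which the median of all tested repeats moved from -0.0046 to -0.61, HERVH-int stood at 0.42 (edgeR adjusted p = 0.225) and LTR7 at 0.17 (0.619). Of 18 alternatives, the test beyond a log2 of 1 aside, HERVH-int kept its call in 15 and LTR7 in 14.

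**Figure D2:**
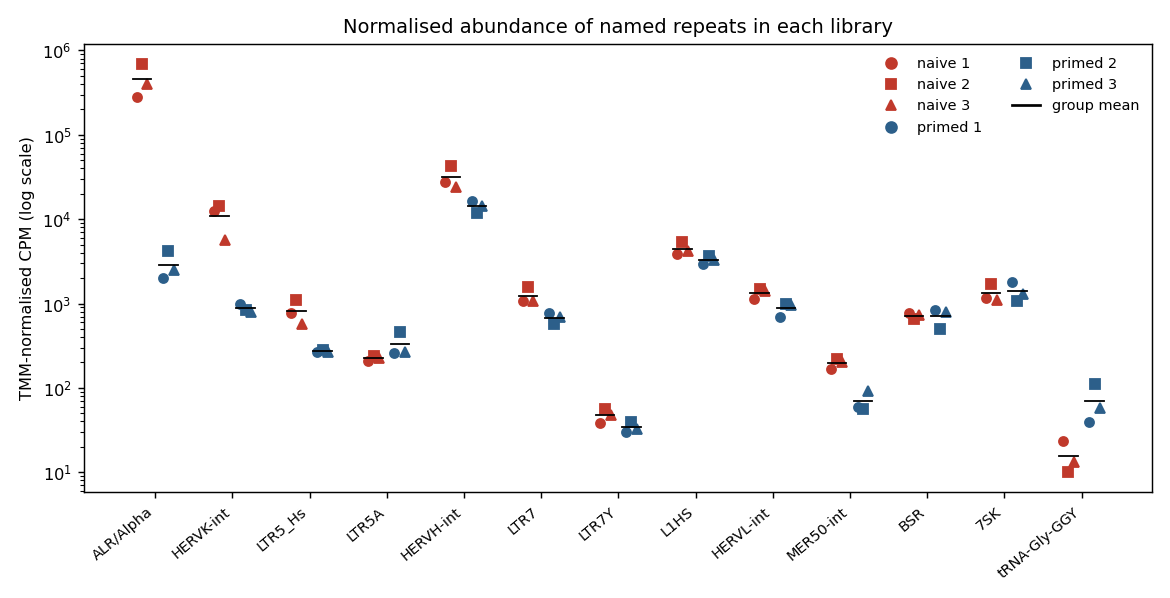
TMM-normalised CPM (log axis) of 13 named repeats in each library; red symbols are naive, blue symbols primed, symbol shape gives the library number and black lines the group means. HERVK-int averages 10797 CPM in naive and 877 CPM in primed libraries, whereas BSR averages 715 and 707 CPM.

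Several further families of retroviral and L1 origin were higher in naive cells with TMM scaling. Over all 1265 named repeats tested, 131 were called higher. The share of members called in the mammalian L1, MLT1 and THE1 and MST lists was near or below that. Of 32 older primate L1 families, 13 rose and 0 fell, with a median log2 change of 0.49 (camera adjusted p = 1.31e-05; adjusted p = 0.684 with an estimated correlation); with library size alone the median was -0.21 and the list did not pass (camera adjusted p = 0.543). Examples are L1P4e (1.64 ± 0.32, SE), L1P4d (1.23 ± 0.21) and L1PB2 (0.82 ± 0.14), with edgeR adjusted p of 0.0148, 0.00959 and 0.00959. The 27 MER4, MER41 and MER61 retroviral families had 7 that rose and 0 that fell, with a median of 0.33 (camera adjusted p = 0.000252; adjusted p = 0.684 with an estimated correlation); with library size alone this became -0.31 (camera adjusted p = 0.883). MER61A (1.07 ± 0.17; edgeR adjusted p = 0.00959) and MER61D (0.95 ± 0.17; 0.0117) were among them. MLT1, an old retroviral group, had 3 of 34 that rose (MLT1G1, MLT1E3 and MLT1M) and all 34 above 0, with a median of 0.31 (camera adjusted p = 1.31e-05; adjusted p = 0.684 with an estimated correlation) that became -0.36 with library size alone (camera adjusted p = 0.637). The mammalian L1 list had 10 of 92 that rose and a median of 0.21 (camera adjusted p = 8.23e-06; adjusted p = 0.684 with an estimated correlation), against -0.46 with library size alone (camera adjusted p = 0.0876). In the THE1 and MST list 1 of 14 rose, MSTA at 0.46 ± 0.13 (edgeR adjusted p = 0.0400), and the list median of 0.37 (camera adjusted p = 0.0104; adjusted p = 0.684 with an estimated correlation) became -0.31 with library size alone (camera adjusted p = 0.681) and did not pass with upper-quartile factors (0.0526). With simple repeats left out, older primate L1 still passed (camera adjusted p = 0.00286), while MER4, MER41 and MER61 (0.0870), MLT1 (0.0870), THE1 and MST (0.166) and mammalian L1 (0.906, with a median of -0.0068) did not. Without primed library 1 the list test no longer passed for older primate L1 (camera adjusted p = 0.0924), mammalian L1 (0.0694), MLT1 (0.0694) and THE1 and MST (0.247). The named single calls were lost in that fit too, where L1P4e gave 1.76 (edgeR adjusted p = 0.0877), L1P4d 1.06 (0.0783), L1PB2 0.69 (0.0656), MER61A 1.02 (0.0701), MER61D 0.87 (0.0877), MLT1G1 0.73 (0.144), MLT1E3 0.52 (0.177), MLT1M 0.45 (0.205) and MSTA 0.43 (0.186). MLT1E3 and MLT1M also missed the threshold without naive library 2 (0.59, 0.0648 and 0.56, 0.0695), and MLT1M without naive library 3 (0.51, 0.0563). MSTA was also lost without naive library 2 (0.45, 0.123), naive library 3 (0.46, 0.0800) or primed library 2 (0.41, 0.0558).

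All 7 young L1 families, L1HS to L1PA7, had positive log2 changes and 0 passed the test by edgeR. L1HS was at 4483 ± 808 CPM in naive and 3295 ± 379 CPM in primed libraries (log2 0.45 ± 0.15, SE; edgeR adjusted p = 0.0692). Their median was 0.36 (camera adjusted p = 0.0558), and -0.38 with library size alone. MER50-int, the internal part of a further retroviral group, rose by 1.43 ± 0.19 (log2, SE, edgeR adjusted p = 0.00443), from 69.3 ± 19.6 to 197 ± 26.3 CPM. It was called in each of the 6 fits without 1 library, and in 17 of all 18 alternatives (highest adjusted p = 0.421). With library size alone it gave 0.80 (edgeR adjusted p = 0.0152).

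Alu elements, the abundant short retrotransposons of primates, shifted as lists by small amounts with 0 single calls by edgeR. All 17 AluS families were below 0, with a median of -0.21 (camera adjusted p = 0.0184; adjusted p = 0.684 with an estimated correlation), and so were 22 of 24 AluY families, with a median of -0.21 (camera adjusted p = 0.0121; adjusted p = 0.684 with an estimated correlation). With library size alone these medians were -0.84 and -0.85. The list calls were lost without primed library 1 (camera adjusted p = 0.221 for AluS and 0.110 for AluY), naive library 1 (0.0907 and 0.0783) or naive library 3 (0.0568 and 0.0509), and for AluS without primed library 3 (0.0757). The mean of AluS less that of other repeats was only -0.05, and without naive library 1 or 3 it was above 0 (0.08 and 0.0373), as was that of AluY without naive library 1 (0.0038). With simple repeats left out both lists passed (camera adjusted p = 1.62e-07 each), with medians of -0.45 for AluS and -0.44 for AluY. Camera on counts kept AluY (adjusted p = 0.0358) and not AluS (0.147). AluSx gave -0.33 (edgeR adjusted p = 0.230), AluYa5 -0.52 (0.0785) and AluYb8 -0.15 (0.502). Among counts outside alpha satellite and ribosomal RNA, Alu took 16.3% ± 0.462 in naive and 20.5% ± 2.88 in primed libraries (SD, n = 3; exact permutation p = 0.1), and L1 took 27.7% ± 0.487 and 26.1% ± 2.93 (exact permutation p = 0.5).

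**Figure D3:**
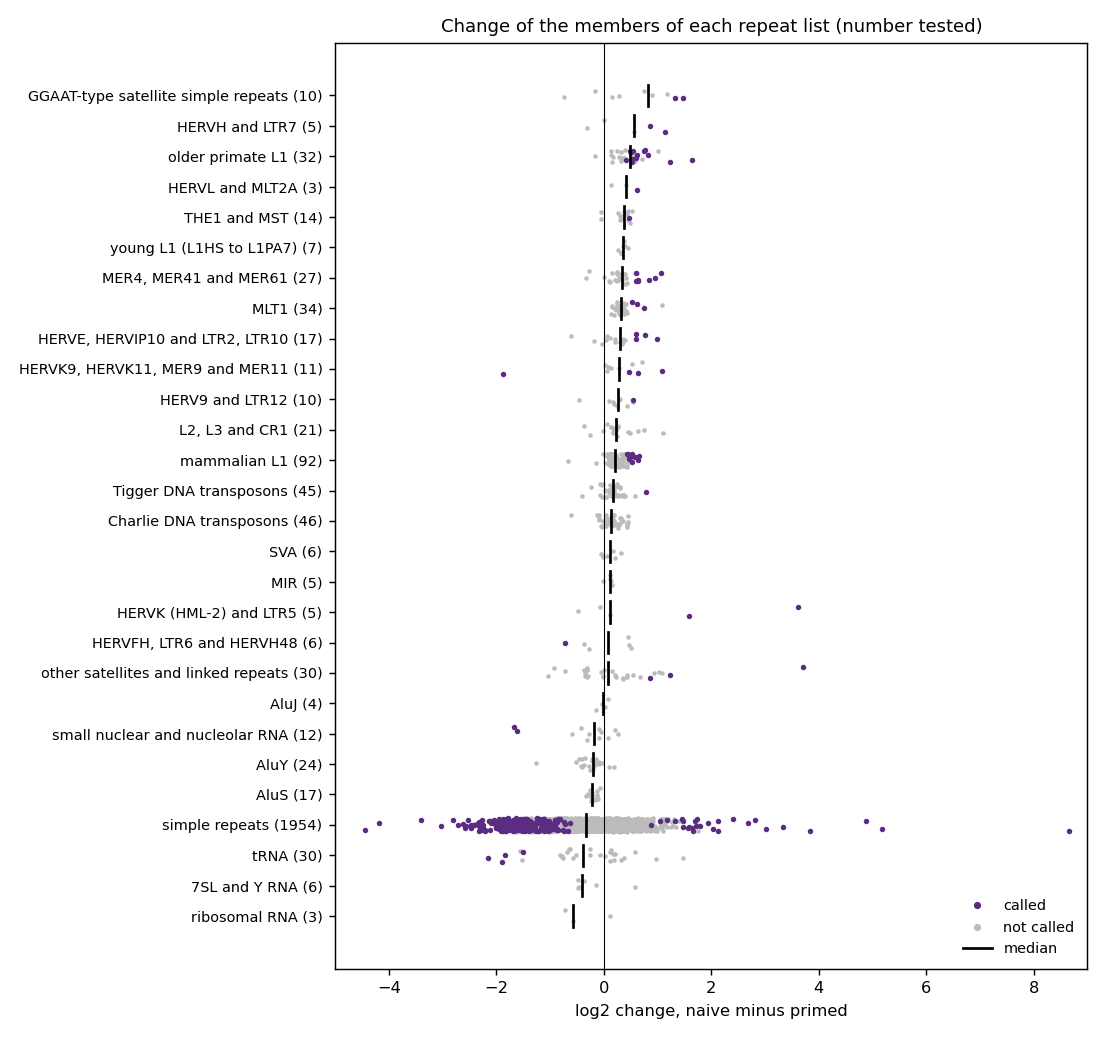
Log2 change (naive minus primed) of the tested members of 28 repeat lists; each dot is a repeat, purple where called by edgeR at an adjusted p under 0.05 and grey otherwise, and the black bar is the list median. Older primate L1 has 13 of 32 members called higher and simple repeats have 235 of 1954 called lower; with library size as the only scaling the median of all repeats is -0.61 and the L1, retroviral and DNA transposon medians fall below 0.

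Of 1954 simple repeats tested, 28 rose, 235 fell and 1691 did not pass, with a median log2 change of -0.34 (camera adjusted p = 5.79e-12; adjusted p = 0.684 with an estimated correlation). With library size alone the median was -0.90, but the list test did not pass and its direction turned to higher (camera adjusted p = 0.288). The median was 0.02 for the 182 units without G or C and -0.76 for the 545 units with a GC content above 66% that also hold A or T. The (GCCCAGC)n repeat fell by 4.18 on the log2 scale (SE 0.45; edgeR adjusted p = 0.000969), from 24.9 ± 9.996 CPM in primed to 1.23 ± 0.598 CPM in naive libraries. In the opposite direction, (GACCCTG)n had 664, 389 and 585 counts in naive libraries 1 to 3 and 1, 0 and 1 in primed libraries 1 to 3. Per TMM-scaled library total this is a ratio of rates of 434, with a 95% counting interval of 120 to 3587. The (AATGG)n repeat, a unit of satellite type, rose by 1.32 ± 0.24 (edgeR adjusted p = 0.0121). With library size alone it gave 0.74 and did not pass (edgeR adjusted p = 0.121). Without primed library 1, 6 simple repeats fell and 1 rose, and (AATGG)n gave 1.31 (edgeR adjusted p = 0.0804), while the (GCCCAGC)n and (GACCCTG)n calls were kept without any 1 library.

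Structural RNAs were lower or did not pass. Of 30 tRNA entries, 4 fell and 0 rose, among them tRNA-Gly-GGY, at 15.5 ± 6.94 CPM in naive and 70.02 ± 37.4 CPM in primed libraries (log2 -1.89 ± 0.36, SE; edgeR adjusted p = 0.0133), and tRNA-Gln-CAA_v (-1.84 ± 0.48; 0.0304). The other calls were tRNA-Ser-TCA(m) (-2.16 ± 0.60; edgeR adjusted p = 0.0393), with overlapping groups, and tRNA-Arg-AGG (-1.50; 0.0275). Of 12 small nuclear and nucleolar RNA entries, 2 fell: U4 (-1.68 ± 0.49; edgeR adjusted p = 0.0462) and U17 (-1.62 ± 0.41; 0.0302), both with overlapping groups. The small nuclear and nucleolar share of counts was 0.177% ± 0.0148 in naive and 0.330% ± 0.0457 in primed libraries (exact permutation p = 0.1). With alpha satellite left out of the total, the difference went from -0.152 to -0.0589 points (exact permutation p = 0.2). Neither list passed (camera adjusted p = 0.249 and 0.339). The 7SK RNA gave -0.08 (edgeR adjusted p = 0.814). Ribosomal RNA took 6.08%, 5.58% and 0.169% of counts in naive libraries 1 to 3 and 17.7%, 4.04% and 8.01% in primed libraries 1 to 3 (exact permutation p = 0.3), so naive library 3 stood apart. The tRNA-Gly-GGY call was kept in each of the 6 fits without 1 library. Without primed library 1 tRNA-Gln-CAA_v gave -1.28 (edgeR adjusted p = 0.298), tRNA-Ser-TCA(m) -1.16 (0.312), tRNA-Arg-AGG -1.50 (0.173), U4 -0.91 (0.395) and U17 -1.48 (0.173). The tRNA-Gln-CAA_v and tRNA-Ser-TCA(m) calls were also lost without naive library 2 (-1.68, 0.0505 and -1.90, 0.0511), that of U17 without primed library 3 (-1.43, 0.0711), that of tRNA-Arg-AGG without naive library 2 (-1.50, 0.0791), naive library 3 (-1.39, 0.0690) or primed library 3 (-1.40, 0.0738), and that of U4 without naive library 2 (-1.53, 0.0668), naive library 3 (-1.40, 0.0646) or primed library 3 (-1.88, 0.0543).

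Over all 3219 repeats tested, 409 changed, 159 higher and 250 lower in naive cells, which is 38.9% higher. Named repeats accounted for 146 of these, 131 higher and 15 lower. That balance depended on the scaling and on the repeats fitted. It was 116 higher and 18 lower with RLE factors, and 79 and 27 with upper-quartile factors. With alpha satellite and ribosomal RNA entries removed under TMM scaling it was 110 and 20. With library size alone it was 13 and 215, a scaling in which the large alpha satellite share lowers every other share in naive libraries. With simple repeats left out it was 31 and 17, where 38 of the 146 calls were shared. With upper-quartile factors 23.3% of 447 changed repeats were higher, and with library size alone 2.60% of 1079. A change beyond a log2 of 1 was supported by edgeR's glmTreat for 5 repeats, of which ALR/Alpha, HERVK-int, ACRO1 and (GACCCTG)n were higher and (GCCCAGC)n lower. The number of calls rested strongly on primed library 1, without which 15 repeats were called, 8 of them named: ALR/Alpha, HERVK-int, LTR5_Hs, HERVH-int, MER50-int, ACRO1 and Zaphod4a higher and tRNA-Gly-GGY lower. That fit leaves primed libraries 2 and 3, and primed library 2 has only 118793 counts. The number of calls was 544 without the shallow primed library 2 and 430 without primed library 3. It was 651 without naive library 1, 178 without naive library 2 and 317 without naive library 3. Groups did not overlap for 977 repeats, 30.4% of those tested, where chance gives 10% for any single repeat. Repeats of a library are not independent, so the share over all of them can lie far from 10% by chance.

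**Figure D4:**
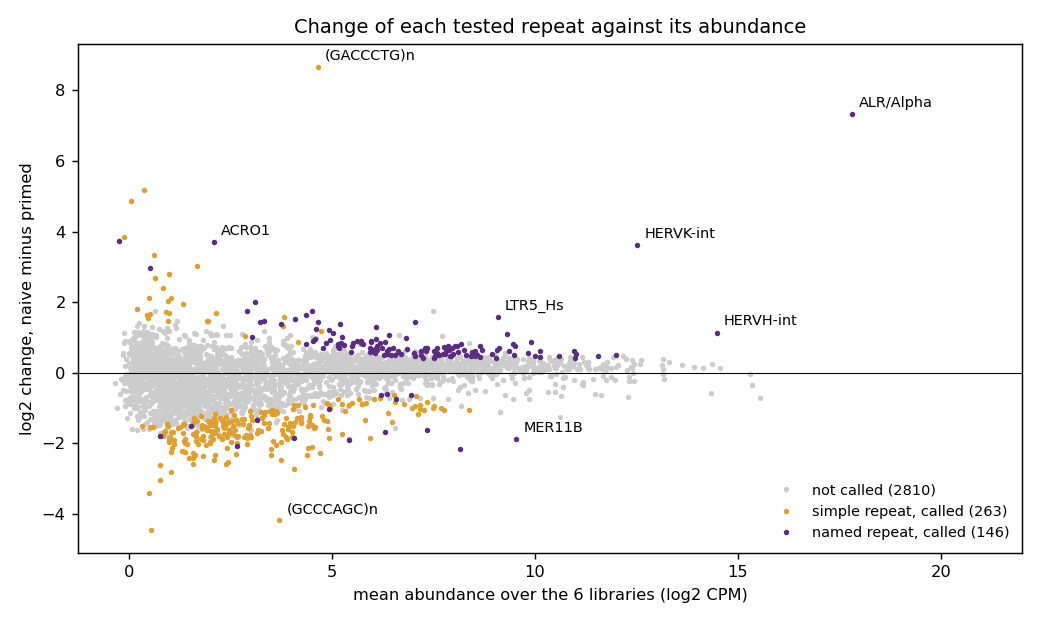
Log2 change (naive minus primed) of each tested repeat against its mean abundance (log2 CPM over the 6 libraries); purple and orange dots are named and simple repeats called by edgeR at an adjusted p under 0.05 and grey dots are not called. Of the named repeats 131 were called higher and 15 lower, and of the simple repeats 28 higher and 235 lower. ALR/Alpha lies at 7.32 and the rarer (GACCCTG)n at 8.66.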

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

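The alternatives that leave out simple repeats or alpha satellite, thin the libraries, run DESeq2 on the main filter or run camera on counts were chosen after seeing the data. The calls for ALR/Alpha, HERVK-int, ACRO1, tRNA-Gly-GGY, (GACCCTG)n, (GCTCGGA)n and (GCCCAGC)n were kept in each alternative in which they were tested, the test beyond a log2 of 1 aside, which called 5 repeats. The rare (GCTCGGA)n was tested in only 12 alternatives and not without primed library 1. It had 0, 1 and 1 counts in naive libraries 1 to 3 and 16, 1 and 10 in primed libraries 1 to 3. Of the 56 repeats the naming rule took, 9 kept their call without primed library 1, 46 lost it with the same direction and 1 was not tested, 31 kept it without naive library 2 (24 lost it), 26 kept it with library size alone (20 lost it, 10 turned), 20 with simple repeats left out (28 lost it) and 2 when thinned (27 lost it, 1 turned); others were not tested there. The cause was not tested except where said.

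All repeats changed: 409, against 1079 with library size alone (28 higher, 1051 lower), 209 with DESeq2, 223 with DESeq2 on the main filter, 860 with no filter on low counts (10175 repeats tested), 48 with simple repeats left out, 2 when thinned to 118793 counts (718 repeats tested), 5 beyond a log2 of 1, and 15 to 651 without 1 library. Named repeats changed: 146, against 228 with library size alone, 273 with the replicate block, 48 with simple repeats left out, 2 when thinned, 90 with DESeq2 on the main filter, 3 beyond a log2 of 1, and 8 to 226 without 1 library. Simple repeats changed: 263, against 851 with library size alone, 110 with DESeq2, 133 with DESeq2 on the main filter, 680 with no filter, 0 when thinned, 2 beyond a log2 of 1, and 7 to 425 without 1 library. Thinning leaves fewer counts and fewer repeats to test, which limits it by construction. Lists passing: 8, against 3 with library size alone, 3 with simple repeats left out, 17 by camera on counts, and 2 to 15 without 1 library. With alpha satellite and ribosomal RNA removed all 8 were kept. Camera with an estimated correlation passed 0 (smallest adjusted p = 0.684). Fry passed 0 (smallest adjusted p = 0.0893), and 12 by its mixed form.

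With the replicate number as a block, 638 repeats changed. Deviations of same-numbered libraries correlated at 0.146, 0.0867 and 0.0659, so not all pairs passed 0.1 and the numbers are not taken to pair libraries; each library correlated best with its own number, a hint from the data and not the design.

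With library size alone, these repeats called higher turned to L1MA1 -0.15, HERVL-int -0.10, HERV9NC-int -0.13, MER11A -0.0295, MER11C -0.22, HERV17-int -0.0121, HERVIP10F-int -0.0157, MSTA -0.23, MLT1E3 -0.0372 and MLT1M -0.13, where the median of all repeats was -0.61. The camera direction turned for mammalian L1, THE1 and MST, MLT1 and simple repeats, although their mean log2 changes minus those of other repeats were 0.31, 0.40, 0.41 and -0.54. It also turned for mammalian L1 with simple repeats left out (0.0182). MER67B turned to 0.0846 when thinned. The share of the 10 most abundant entries, 20.9 points higher in naive libraries, differed by -3.13 points with alpha satellite left out of the total, since alpha satellite is one of them, and the small nuclear and nucleolar RNA difference went from -0.152 to -0.0589 points. No long non-coding or mitochondrial alternative was run, since no entry carries such a name. Changes in repeats with under 3 counts in primed library 2 (25.3 CPM) rest on the other libraries.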

Other observations

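The HERVE, HERVIP10, LTR2 and LTR10 list had 4 of 17 higher (HERVE_a-int, HERVE-int, HERVIP10F-int and HERVIP10FH-int), with HERVE_a-int at 0.99 ± 0.16 (log2, SE; edgeR adjusted p = 0.00959), with a list median of 0.31 (camera adjusted p = 0.0517). Tigger DNA transposons had 1 of 45 higher, Tigger6 (list median 0.18, camera adjusted p = 0.0517) and Charlie DNA transposons 0 of 46 (median 0.14, 0.116). The L2, L3 and CR1 list had 0 of 21 called (median 0.22, camera adjusted p = 0.151), HERV9 and LTR12 1 of 10 higher, HERV9NC-int (list median 0.26, 0.151), MIR 0 of 5 (median 0.11, 0.667) and SVA 0 of 6 (median 0.11, 0.726). With library size alone the medians of these lists fell to between -0.57 and -0.35, where all repeats had -0.61. HERVL and MLT2A had 1 of 3 higher, HERVL-int (list median 0.42, camera adjusted p = 0.186; -0.24 with library size alone), and the GGAAT-type satellite units 2 of 10, (AATGG)n and (GGAAT)n (list median 0.82, 0.106). The GGAAT-type list passed as higher with library size alone (median 0.22, camera adjusted p = 0.0161) and by camera on counts (adjusted p = 0.0130). The HERVFH, LTR6 and HERVH48 list had 1 of 6 lower, LTR6A (list median 0.09, camera adjusted p = 0.712), and the 7SL and Y RNA list 0 of 6 (list median -0.41, 0.175). Without primed library 1 these single calls did not pass: HERVE_a-int gave 0.87 (edgeR adjusted p = 0.0804), HERVE-int 0.73 (0.221), HERVIP10F-int 0.52 (0.218), HERVIP10FH-int 0.46 (0.263), Tigger6 0.59 (0.199), HERV9NC-int 0.49 (0.157), HERVL-int 0.46 (0.199), (AATGG)n 1.31 (0.0804), (GGAAT)n 1.33 (0.312) and LTR6A -0.50 (0.209). Without naive library 2 the calls of HERVE-int, HERVIP10F-int, HERVIP10FH-int, Tigger6, HERV9NC-int, HERVL-int, (GGAAT)n and LTR6A were lost too, with edgeR adjusted p between 0.0562 and 0.0887. The calls of (GGAAT)n and HERVE-int were also lost without primed library 2 (1.46, 0.0539 and 0.70, 0.0682), that of HERVIP10FH-int without naive library 3 (0.61, 0.0572), and that of (GGAAT)n without naive library 3 (1.21, 0.135) or primed library 3 (1.69, 0.1002).

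Within the HERVK9, HERVK11, MER9 and MER11 list, members went opposite ways: 3 of 11 rose and 1 fell (list camera adjusted p = 0.267). MER11A rose by 0.63 ± 0.15 (edgeR adjusted p = 0.0242) and HERVK11-int by 1.09 ± 0.26 (0.0247), while MER11B fell by 1.88 on the log2 scale (SE 0.55, adjusted p = 0.0467), with 17121, 44 and 10683 counts in primed libraries 1 to 3 against 2653, 5474 and 2562 in naive libraries 1 to 3 and overlapping CPM. With library size alone MER11A stood at -0.03 (edgeR adjusted p = 0.936), HERVK11-int at 0.40 (0.231) and MER11B at -2.51 (9.46e-17). Without primed library 1 the values were 0.46 (edgeR adjusted p = 0.186) for MER11A, 0.88 (0.177) for HERVK11-int and -1.12 (0.304) for MER11B. HERVK11-int also missed the threshold without primed library 3 (1.07, 0.0556), and MER11B without primed library 3 (-1.96, 0.0677) or naive library 3 (-1.57, 0.0535).

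The tests below on the other satellites, the near-identical families and GC content were chosen after the result was seen, as was the use of the fits without primed library 2 as a test, fits that were planned as alternatives. For the high alpha satellite RNA in naive libraries, carry-over of genomic DNA or of every satellite was taken to raise other satellites by a log2 of 1 or more. The 30 tested, with the called ACRO1, HSATI and CER among them, had a median of 0.0759 (95% bootstrap interval -0.31 to 0.39, over repeats that are not independent). These 30 did not rise as a set, and the GGAAT-type units, not among them, had a median of 0.82. TMM scaling would remove a rise shared equally by all repeats. Such a rise would also not set alpha satellite (7.32) above the median of all tested repeats (-0.0046). How genomic DNA would be spread over the repeats was not examined, so the test cannot decide on genomic DNA that adds to them unequally. Keeping reads that map to many near-identical copies in naive libraries only was taken to raise L1HS, L1PA2, AluYa5, AluYb8, SVA_E and SVA_F by a log2 of 1 or more. Their median was 0.24 (95% bootstrap interval -0.33 to 0.41), so these 6 families as a set did not rise with alpha satellite. HERVK-int (3.62) and LTR5_Hs (1.59), whose near-identical copies can share reads, were not among the 6 and rose by more than 1. The test therefore leaves this explanation open. Without the shallow primed library 2 the alpha satellite change was 7.68 (edgeR adjusted p = 7.21e-05), so its depth does not account for the difference. The difference of cell state that the labels name stays open and was not tested. A difference in fractionation or sequencing between the sets of libraries was not tested, as the labels give no batch.

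For the lower simple repeats, the small depth of primed library 2 is not needed: without that library 91.2% of 364 changed simple repeats were still lower. A dependence on GC content has the values it needs: across 1954 simple repeats, which are not independent, the log2 change fell with the GC percent of the unit (Spearman rho = -0.400, between -0.487 and -0.323 when any 1 library was left out), and units without G or C had a median of 0.02 (-0.05 to 0.09). Counts in GC-rich units per count in units without G or C were 1.68, 1.72 and 1.18 in naive libraries 1 to 3 and 2.47, 1.43 and 2.31 in primed libraries 1 to 3 (exact permutation p = 0.3), so primed library 2 lay within the naive range. A GC bias of library preparation or a change in transcripts that carry GC-rich repeats could each give this, and these data do not separate them. The GC content of L1, Alu and other named repeats was not examined, so its part in their changes was not tested.

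The 6 libraries can be split into 3 and 3 in 10 ways, and 1 of them, the naive and primed split itself, called as many as 409 repeats; the highest other split called 1. With 10 splits no share under 0.05 can be reached.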
